A study of Homo sapiens with 2 samples.

How the data were processed

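Gene expression was measured on single-colour oligonucleotide arrays (Phalanx Human OneArray) in 2 samples of cells labelled HepG2, a human liver cancer line. 1 sample had received polaprezinc, a chelate of zinc and L-carnosine, at 16 µg/ml and the other had received 0 µg/ml, both for 7 days, per the labels. The labels also state that total RNA was extracted with TRIzol, amplified and labelled with Cy5. The array is described by the submitters as carrying 31741 mRNA probes for 20672 genes; 28264 probes were given for each array in the tables used here.

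The authors deposited 1 raw intensity and 1 detection p-value per probe and array, per the file headers. The scanner, the image software, any background step and the method behind the detection p-value are not given in the sources used here. The raw intensities were whole numbers from 15 to 580295 in the 0 µg/ml sample and from 12 to 540644 in the 16 µg/ml sample, with none at or below 0. The authors also deposited a processed intensity per probe, on a linear scale. Set against the raw intensity it was the same multiple for every probe of an array, 0.552 in the 0 µg/ml sample and 0.613 in the 16 µg/ml sample, so it holds 1 scaling factor per array and no background correction of single probes. The median processed intensity was 693 and 716. The rule behind the factors stays unknown.

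The raw intensities were corrected with the normexp method of limma 3.58.1 under R 4.3.3 on the signal alone, with an offset of 50, then quantile-normalized between the 2 arrays and taken to log2. A probe counted as detected where the deposited detection p-value was below 0.05. Probes were named through the platform annotation of 2017, which gave 1 gene for 25893 probes and named none for 2371; no probe had several. All 25893 Entrez identifiers matched a gene of the RefSeq table for GRCh38.p14, and no symbol needed updating. No genome positions were used. Genes with a probe detected on at least 1 array were kept, 12111 of 19090, and each took its probe with the highest mean signal. Of these genes, 11313 were detected on both arrays, 628 at 0 µg/ml only and 170 at 16 µg/ml only. For a gene detected on 1 array only, the fold is a lower bound. No fold is given where that bound is under 1. The bound was computed from the bright array's value against the higher of the lowest detected signal on the other array and the gene's own signal there. Bounds and folds are on the normalized log2 scale, and the offset understates the change of dim genes.

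The design has 1 sample per dose, so no error between replicates exists, and no test between the doses was made. Differences describe these 2 arrays, and the number of arrays limits the precision. A fixed rule of size was used: a gene was counted as higher or lower where the 2 samples differed by at least 2-fold. For each of 32 gene lists, 5 of them markers of cell types, the median log2 difference was computed. For the 28 lists with at least 5 measured genes it was placed among 10000 random lists of the same size, drawn from 20 bins of equal gene number so as to match mean signal. A median outside the central 95% of these is said to stand apart. Were the genes of a list unrelated, 1.4 of 28 lists would do so by chance. Genes of a list can vary together between any 2 cultures, so more could stand apart without an effect of the dose. The only internal view of measurement error came from genes with more than 1 detected probe. The design, the lists, the size rule and the rule for named genes were fixed before the data were examined.

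The genes named were, first, the 10 with the largest positive and the 10 with the largest negative difference among genes detected on both arrays, at or above the median signal of such genes and with no other detected probe of opposite sign. Symbols of uncharacterised loci were passed over. The others were the 2 members of each list with the largest absolute difference, 20 genes set in advance, and up to 5 genes per direction with the largest bound. Genes named outside this rule are marked as chosen after their values were seen.

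The procedure was tested on simulated data. The 0 µg/ml array was set against a copy of itself with random noise of SD 0.249 (log2), the robust spread of the real differences, with 200 genes changed and a list of 20 genes shifted. Among 11946 genes, the 2-fold rule recovered 98.0% of 100 genes changed by 1.5 on the log2 scale and all of the 100 changed by 2.5. It called 1 of 11726 unchanged genes, and 6 of 200 unshifted lists of 20 genes stood apart. Noise was drawn from a normal distribution, which has shorter tails than single spots can have. It was independent between probes and of the same size at every signal level, so the rates for unchanged genes and unshifted lists follow from these settings. Lists of genes that vary together were not simulated. The copy kept the detection p-values of the 0 µg/ml array, so calls by a bound were not tested.

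The alternatives were no background correction, a background inferred from the detection p-values (limma's nec), an offset of 16, median scaling or cyclic loess between arrays, detection on both arrays, a detection p-value below 0.01, no filter, the mean over a gene's probes, the authors' processed intensities, and thresholds of 1.5-fold and 3-fold. A restriction to genes at or above the median signal was added after seeing the data. Leaving out technical arrays was not possible because 1 value per probe and sample was given. The probes without a named gene were left out of all gene counts.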

Results

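Messenger RNA levels were compared between 2 samples of cells labelled HepG2, a human liver cancer line, 1 kept with polaprezinc at 16 µg/ml for 7 days and 1 kept at 0 µg/ml. Each was measured on a single array, and no value below has a replicate. The median raw intensity over 28264 probes was 1255 at 0 µg/ml and 1169 at 16 µg/ml. At a detection p-value below 0.05, 16377 probes (57.9%) were detected at 0 µg/ml and 15598 (55.2%) at 16 µg/ml. The log2 raw intensities of the 2 arrays correlated across probes with a Pearson r of 0.992; probes are not independent replicates. The median log2 ratio of raw intensity over all probes, 16 over 0 µg/ml, was -0.11. After normalization, the median difference over the 12111 genes kept was 0.0087.

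The series title names liver fibrosis and proliferation as its subject, and the single comparison the design holds is 16 against 0 µg/ml. MT1E and MT1F, metallothionein genes whose small proteins bind zinc, had the 2 largest positive differences among genes detected on both arrays. MT1E was 6.11-fold higher and MT1F 4.20-fold higher at 16 µg/ml. The MT1F fold is uncertain, since its spot at 0 µg/ml had a detection p-value high for its signal. SLC39A10, which imports zinc, was 2.37-fold lower. Few other genes passed the size rule: 99.0% of 12111 genes were not called past 2-fold. Genes detected on 1 array only entered by their lower bound, so some of the uncalled ones could differ by more. In all, 37 genes were at least 2-fold higher at 16 µg/ml (34 detected on both arrays and 3 by their bound) and 82 were at least 2-fold lower (55 on both arrays and 27 by their bound). With the background taken from the detection p-values the counts were 101 and 133, and at a threshold of 1.5-fold they were 376 and 281, which turns the imbalance. No test stands behind these counts, since each dose has 1 sample.

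**Figure D1:**
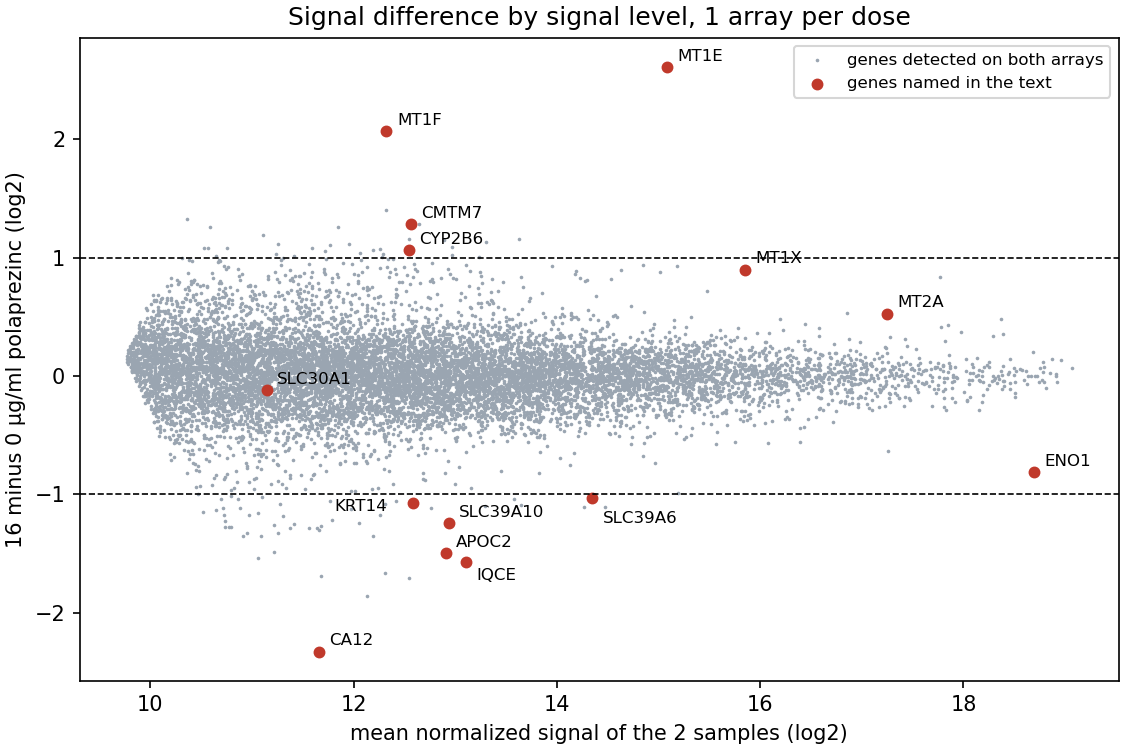
Log2 difference (16 minus 0 µg/ml) against mean normalized log2 signal, 1 point per gene detected on both arrays, with dashed lines at 2-fold. MT1E and MT1F lie at 2.61 and 2.07, above all other genes shown, and SLC39A10 lies at -1.24.

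Zinc buffering and export genes stood apart as a group. Of 10 list members with a probe, 5 were detected, and their median difference was 0.90 on the log2 scale, above the 10000 random lists, of which the central 95% ran from -0.21 to 0.21. MT1E went from a raw intensity of 14837 to 82841 (log2 difference 2.61) and MT1F from 2583 to 9854 (2.07). MT1F had a detection p-value of 0.0059 at 0 µg/ml, whereas ACTA2, with a raw intensity of 2595 there, had 0.00019. MT1X was 1.86-fold higher (0.90) and MT2A 1.44-fold higher (0.53), both short of 2-fold. The probes of MT1G, and of MT1B and MT1M, which were named after their values were seen, were not well above background in either sample. The remaining detected member, the zinc exporter SLC30A1, was at -0.12. Each of the 4 detected metallothioneins had 1 detected probe, and their closely similar sequences leave open how far the probes share signal.

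The other zinc transporters did not stand apart. The median over 15 measured genes was -0.024, at percentile 35.4 of the random lists. Both members past 2-fold were importers of the ZIP family. SLC39A10 was at -1.24 (raw 12749 and 4788). SLC39A6 was 2.04-fold lower by its brighter probe (-1.03), its second probe gave -0.21, and averaging the probes ended the 2-fold call. Of the genes for carnosine, histidine and peptide handling, 3 of 8 with a probe were detected, with a median of -0.047. That is the value of CARNS1, which makes carnosine. The carnosine-cleaving CNDP1 and CNDP2 were not well above background in either sample. These 3 genes were named after their values were seen. The peptide and histidine transporter SLC15A4 was at 0.20 and SLC15A2 at -0.073.

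Among the other genes with large positive differences at or above the median signal, CMTM7 was 2.44-fold, TMEM145 2.24-fold and EPS8L3 2.23-fold higher at 16 µg/ml. LRCH4 was 2.22-fold higher by its brighter probe, its second probe gave a log2 difference of 0.15, and averaging the probes ended the 2-fold call. SLC17A4 was 2.19-fold, C1QC 2.03-fold and ACTR3C 2.01-fold higher. ACTR3C was just short of 2-fold with median scaling and with the authors' processed intensities. CYP2B6, a drug-metabolizing cytochrome P450, was 2.09-fold higher. The other probe of CYP2B6 was not detected in either sample. UNC13A, at 1.99-fold, closed the list of 10 just short of the size rule, which it passed with the background taken from the detection p-values.

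Among the genes with large negative differences, IQCE was 2.97-fold lower by its brighter probe, with -0.34 in the second. APOC2, an apolipoprotein that activates lipoprotein lipase, was 2.83-fold lower. FAM131B was 2.17-fold, TNKS1BP1 2.16-fold, TMOD3 2.15-fold, NOS1AP 2.15-fold and ARHGDIG 2.13-fold lower. KRT14, a basal keratin, was 2.10-fold lower and PLEKHG2 2.08-fold lower. The second probe of TMOD3 gave -0.023 and that of PLEKHG2 -0.39. Averaging the probes ended the 2-fold calls of IQCE, TMOD3 and PLEKHG2. CA12, a zinc-dependent carbonic anhydrase, had the largest negative difference of all genes detected on both arrays, 5.03-fold (raw 7648 and 1351). It lay below the median signal and was named after its value was seen. Its other probe was not detected in either sample.

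Genes detected on 1 array only gave bounds. At 16 µg/ml, G6PC3 was at least 3.96-fold higher, PADI1 at least 3.13-fold, LRRC41 at least 2.65-fold, SYNDIG1 at least 1.88-fold and ZNF833P at least 1.72-fold higher. CCDC60 was at least 3.90-fold lower, BAIAP3 at least 3.16-fold, PAGE5 at least 3.04-fold, OR51B4 at least 2.93-fold and PLPP4 at least 2.91-fold lower. Each of these 10 genes had 1 detected probe. The probes of G6PC3 and LRRC41 read 30 and 41 in raw intensity at 0 µg/ml, with detection p-values of 0.910 and 0.954. Of the other probes within 5 units of their raw intensity on that array, 8 of 86 and 2 of 221 had detection p-values as low, so these spots were unusual and their bounds are uncertain. The bound of LRRC41 fell short of 2-fold when the detection p-value had to be below 0.01. PADI1 read 1964 at 0 µg/ml, above the lowest detected raw intensity there (807), yet was not detected. Likewise PAGE5 read 929 at 16 µg/ml, where the lowest detected was 855. The bounds of PADI1 and PAGE5 are therefore uncertain as well.

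**Figure D2:**
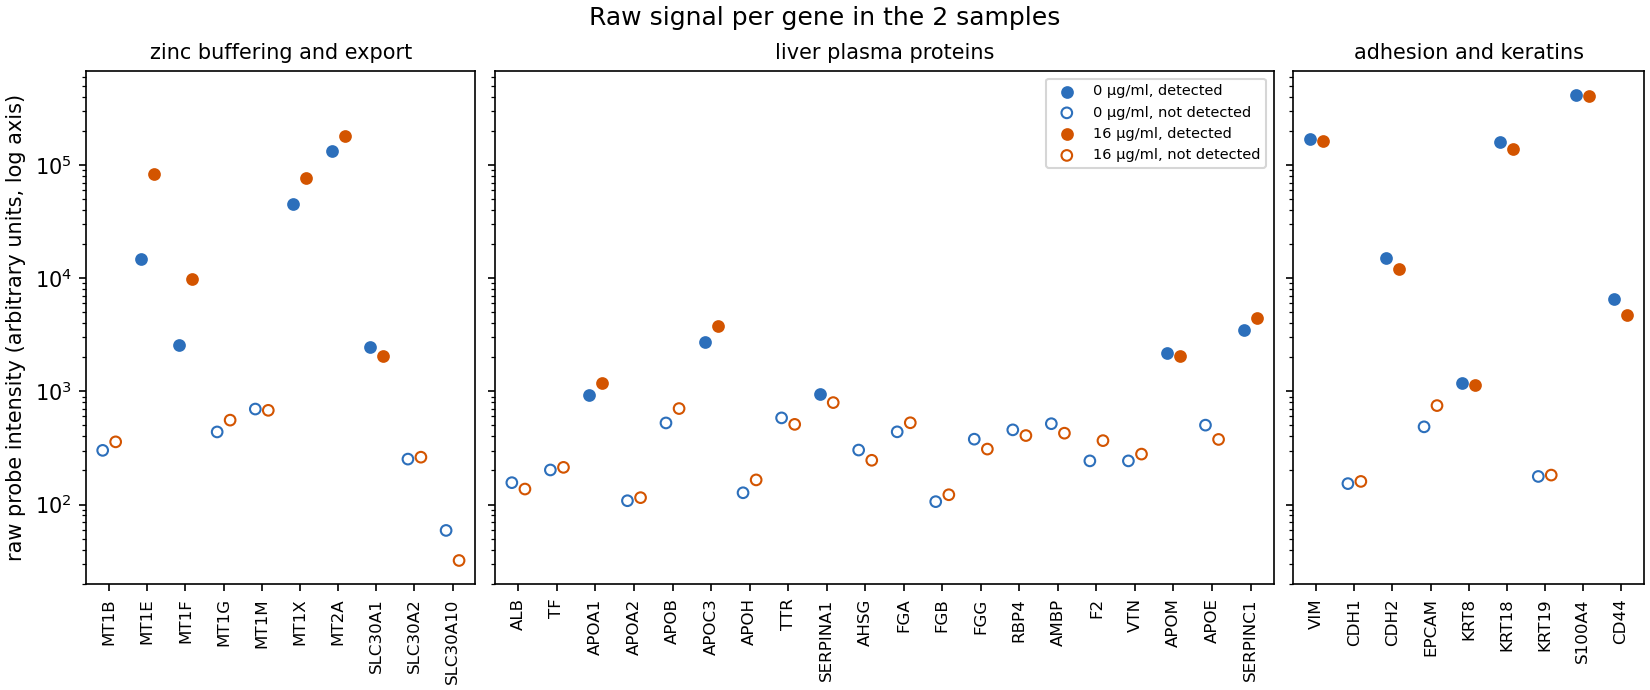
Raw probe intensity on a log axis for genes of 3 lists in the 0 µg/ml sample (blue) and the 16 µg/ml sample (orange), filled where detected and open where not. MT1E, MT1F, MT1X and MT2A are higher at 16 µg/ml, ALB and most other liver plasma proteins are open in both samples, and VIM is filled in both.

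Plasma protein and hepatocyte marker genes were mostly not well above background in either sample. Of 20 genes on the plasma protein and hepatocyte marker lists with a probe, 4 were detected on both arrays and 15 on neither. Over all genes with a probe, 59.3% were detected on both. Of 13 urea cycle, gluconeogenesis and amino acid genes with a probe, 7 were detected on both arrays (53.8%). The share was lower for drug and bile metabolism genes (8 of 25, 32%) and acute phase genes (5 of 16, 31.25%). The urea cycle genes CPS1 (raw 48475 and 40459) and ASS1 (68889 and 64862) were bright in both samples. The cytochrome P450 gene CYP1A2 read 36886 and 36920, but its detection p-values of 0.00072 and 0.00029 were high for that signal. COL5A1, for example, read 36888 at 0 µg/ml with a detection p-value of 5.4e-07. The CYP1A2 spots were thus unusual and their signal is uncertain. CPS1, ASS1, CYP1A2 and COL5A1 were named after their values were seen. ALB, the albumin gene, read 156 and 137 in raw intensity, and the oncofetal marker AFP was also not well above background. HepG2 is known for secreting albumin, alpha-fetoprotein and apolipoproteins. The plasma protein list had 5 measured genes and a median of 0.43 (percentile 99.3 of the random lists), so it stood apart. APOC3 was at 0.61 and SERPINC1 at 0.52, while SERPINA1 was not detected at 16 µg/ml and was at least 1.05-fold lower there. APOA1 was at 0.43 by its brighter probe and -0.23 by the other, and the list no longer stood apart when probes were averaged (median 0.10, percentile 75.2) or undetected genes were let in (median 0.16). Of the hepatocyte markers alone, APOA1 and SERPINA1 were the 2 measured genes of 9 with a probe, with a median of 0.13, or 0.18 with SERPINA1 at its bound. The drug and bile metabolism list stood apart with a median of 0.34 over 11 of 25 genes with a probe (percentile 99.96), or 0.21 with genes detected once set at their bounds. Its largest members were CYP2B6 at 1.07 and UGT1A1, which conjugates bilirubin, at 0.64. With the background taken from the detection p-values it did not stand apart (median 0.20, percentile 95.2), nor with undetected genes let in (median 0.080, percentile 73.4).

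Acute phase genes had 5 of 16 members detected and a median of 0.13 (percentile 75.8), with the haem-binding HPX at 0.48 and CRP at 0.23. Urea cycle, gluconeogenesis and amino acid genes had a median of 0.094 over 8 genes (percentile 81.1). FBP1, a gluconeogenic phosphatase, was at 0.72 and PCK2 at 0.41, with 0.47 in its second probe. Neither list stood apart.

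Stress response genes gave 1 list that stood apart. The unfolded protein and integrated stress response list had a median of 0.15 over 21 measured genes (percentile 99.65 of the random lists), with 15 genes above 0 and 6 below, and none past 2-fold. PPP1R15A, which restores translation after stress, was at 0.80 and DDIT3, a stress-induced transcription factor, at 0.61. Antioxidant genes regulated by NRF2 had a median of 0.082 over 18 genes (percentile 95.7). AKR1C1 was at 0.53 (0.35 in its second probe), GCLC, which makes glutathione, at -0.41, and the haem oxygenase HMOX1 at 0.13. Heat shock genes had a median of -0.058 over 17 genes (percentile 9.94), or -0.028 with genes detected once at their bounds. CHORDC1, a co-chaperone, was at -0.63 with -0.21 in its second probe, and HSPA4L was detected at 0 µg/ml only. With probes averaged the list stood apart (median -0.17, percentile 0.030).

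For proliferation, no member of the 2 cell cycle lists was past 2-fold. The mitosis list had a median of -0.098 over 23 genes, with 15 of 23 below 0, at percentile 2.60, just inside the central 95%. It lay outside with median scaling, cyclic loess, detection on both arrays, a detection p-value below 0.01, no filter and the mean over probes. The same held for the authors' processed intensities (median -0.10, percentile 1.62) and for genes at or above the median signal. It stayed just inside with no background correction, the background from detection p-values and an offset of 16. All settings use the same 2 arrays. KIF11, a spindle motor, was at -0.55, TOP2A at -0.42 and the proliferation marker MKI67 at -0.35. The DNA replication list had a median of -0.045 over 22 genes (percentile 12.3). E2F1 was at 0.57, MCM6, part of the replicative helicase, at -0.45 and CCND1 at -0.0044. MYC was at -0.22.

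The p53 target list had a median of 0.13 over 17 genes (percentile 95.4), or 0.045 with genes detected once at their bounds. GDF15 was at 0.61, PPM1D at -0.46, and CDKN1A, which halts the cell cycle, at 0.19 with 0.35 in its second probe. Apoptosis regulators had a median of 0.099 over 16 genes (percentile 91.3), or 0.070 with bounds. BAK1 was at 0.81 by one probe and -0.15 by the other, and BCL2L1 was at 0.38. Immediate early genes had a median of 0.15 over 10 genes (percentile 97.1), with KLF6 at 0.41 (0.29 in its second probe) and EGR1 at -0.41.

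For fibrosis, none of 24 measured genes of matrix, matrix turnover and TGF-beta signalling was past 2-fold, and the list median was -0.063 (percentile 13.8), or 0 with genes detected once at their bounds. The collagen COL1A1 was at 0.051, fibronectin FN1 at 0.048, the protease inhibitor TIMP1 at -0.037, ACTA2 at 0.16 and the protease MMP2 at 0.49. TGFB1 was detected at 0 µg/ml only, though its raw intensity was 816 there and 853 at 16 µg/ml, so no fall is shown. The receptor TGFBR1 was at -0.73 with -0.42 in its second probe. SMAD3, which carries the receptor signal, was at -0.65 by its brightest probe and at -0.13 and 0.13 by the others. The probe at -0.13 was detected on 1 array only. Adhesion genes had a median of -0.014 over 16 genes (percentile 34.4). OCLN was at 0.88, ZEB1 at -0.48 (-0.043 in its second probe) and VIM at 0.0048, and CDH1 was not well above background in either sample.

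**Figure D3:**
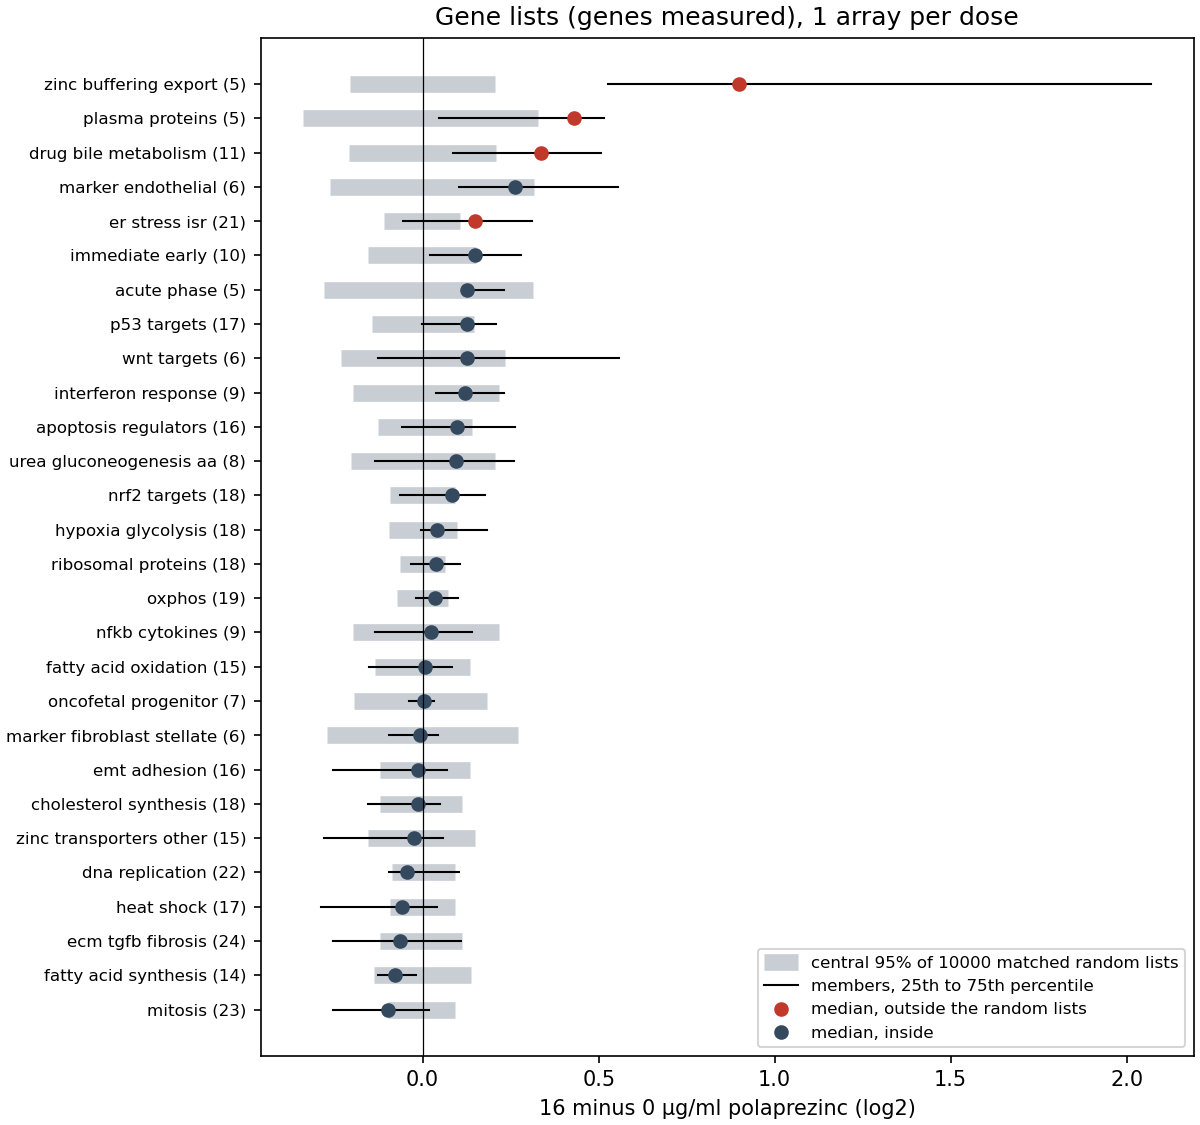
Median log2 difference (16 minus 0 µg/ml) of the 28 ranked gene lists as points, with the interquartile range of the members as lines and the central 95% of 10000 matched random lists as grey bars. The zinc buffering and export list lies at 0.90, and 4 lists (red) lie above their grey bars.

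Lists of lipid, energy and ribosomal genes did not stand apart in the chosen setting. Fatty acid synthesis genes had a median of -0.079 over 14 genes (percentile 12.7), with GPAM, which starts triglyceride synthesis, at -0.86 (-0.59 in its second probe) and ACACA at -0.42. Fatty acid oxidation genes had a median of 0.0058 over 15 genes (percentile 50.2), with the lipid droplet protein PLIN2 at 0.80 and ANGPTL4 at 0.42. Cholesterol synthesis genes had a median of -0.014 over 18 genes (percentile 42.4), or 0.00077 with bounds, with INSIG1 at -0.37 and 0.18 in its second probe. STARD4 was detected at 0 µg/ml only. Hypoxia and glycolysis genes had a median of 0.039 over 18 genes (percentile 79.9). ENO1, a glycolytic enzyme, was at -0.81, and NDRG1 was at 0.31. Respiratory chain genes had a median of 0.036 over 19 genes (percentile 83.1), with COX5A at 0.31 and COX4I1 at -0.26. Ribosomal protein genes had a median of 0.037 over 18 genes (percentile 87.1; with median scaling 0.14, percentile 98.1), with RPS19 at 0.57 and RPS6 at -0.18.

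Signalling lists did not stand apart either. NF-kB cytokine genes had a median of 0.023 over 9 genes (percentile 53.6). The chemokine CXCL8 was at 0.85, and CXCL1 was at least 1.14-fold lower. Interferon response genes had a median of 0.12 over 9 genes (percentile 87.0), with OAS2 at 0.49 and ISG15 at 0.33. Beta-catenin targets had a median of 0.13 over 6 genes (percentile 84.5). LEF1 was at 0.98, short of 2-fold here and past it under 5 of the other settings, and ZNRF3 was at 0.62 with -0.60 in its second probe. Oncofetal and progenitor genes had a median of 0.0046 over 7 genes (percentile 52.6), or 0 with bounds, with CD24 at -0.26. IGF2 was detected at 0 µg/ml only, though its raw intensity was 2331 there and 2285 at 16 µg/ml.

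The fibroblast and endothelial marker lists did not stand apart, and the leukocyte and bile duct marker lists had too few measured genes to be ranked. Fibroblast and stellate cell markers had a median of -0.0083 over 6 genes (percentile 45.1), or 0 with bounds, with RGS5, a pericyte marker, at -0.74. Endothelial markers had a median of 0.26 over 6 genes (percentile 94.6), with PECAM1 at 0.67 and KDR at 0.63. Of the leukocyte markers, 4 of 9 genes with a probe were detected, with a median of 0.22, among them CD14 at 0.30 and TYROBP at 0.29. The bile duct keratin KRT7 was the only detected bile duct marker of 7 with a probe, at 0.16.

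The agreement of probes for the same gene gives the only measure of error within these arrays. Of 2893 genes with a second detected probe, 1849 (63.9%, exact 95% interval 62.1 to 65.7) had both probes on the same side of 0. The correlation of the 2 differences across genes was 0.22, and genes are not independent replicates. Of the 18 genes past 2-fold with a second probe, 11 had that probe in the same direction, and 1 was past 2-fold in it as well.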

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

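The tests of this part on liver genes, metallothioneins and second probes were chosen only after the results they concern had been seen.

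Probes for which the platform annotation named no gene were in no comparison above, and some of them differed between the samples. Of 2371 such probes, 1133 were detected on both arrays, of which 12 were at least 2-fold lower and 8 at least 2-fold higher at 16 µg/ml. The largest differences were -1.80 on the log2 scale (raw 15441 and 3961) and 1.75 (raw 1313 and 4088).

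Plasma protein and hepatocyte marker genes were mostly not well above background in samples labelled HepG2. The shares of probed genes detected on both arrays were 32% for drug and bile metabolism and 31.25% for acute phase genes. For urea cycle, gluconeogenesis and amino acid genes the share was 53.8%. Among these last, CPS1 and ASS1, chosen after their values were seen, were bright in both samples. A general failure of labelling or hybridisation is argued against, since 94.87% of the ribosomal protein and respiratory chain genes with a probe were detected on both arrays. Of the plasma protein and hepatocyte marker genes with a probe, 20% were, which is the pattern itself and tests no explanation of it. Other genes also bear on what the cells are. VIM (raw 169068 and 162611), S100A4 (420546 and 409325) and the keratin KRT18 (158886 and 138321) were bright in both samples. CDH1, EPCAM and KRT19 were detected in neither. Of these, all but VIM and CDH1 were chosen after their values were seen. Another cell line and expression lost in culture both stay open, because no reference profile of HepG2 was used here. Both doses showed it, so no biological explanation from the design was tested.

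The higher metallothionein signal at 16 µg/ml is not explained by scaling or a trend with signal level. Over the 11 settings that ranked it, the zinc buffering and export list had a lowest percentile of 99.99. Cross-hybridisation among metallothionein probes cannot be told apart from separate changes of each gene: 2 of the 7 genes with a probe were at least 2-fold higher, all 4 detected ones were higher, and 3 were not detected. A response to the zinc in polaprezinc may account for the pattern, which rests on 1 sample per dose. The only detected zinc exporter of the list, SLC30A1, was not higher (-0.12).

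Single genes past 2-fold may in large part be noise of single probes. Over the 18 such genes with a second detected probe, the second probe's median difference, signed by the direction of the first, was 0.09432, against 1.09 for the first. In 11 of the 18 it had the same direction. The first probe was selected as past 2-fold, so a smaller difference in the second follows in part from that choice. The second was also the dimmer probe, where the offset understates change. How large the part of noise is therefore stays open. Probes that read different transcripts of a gene could give the same picture and stay open. The call of a gene with 1 detected probe therefore has no internal check.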

How the results depend on the processing

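The restriction to genes at or above the median signal was chosen only after seeing the data; all other settings were planned. Of 295 list values under the alternatives, 277 kept their side of the random lists, 4 no longer stood apart, 14 newly did and 0 reversed. No named gene past 2-fold changed sign. For the 10 highest and 10 lowest, the naming rule required detected probes of 1 sign, so averaging probes could not reverse them. Every setting also used the same 2 arrays. The cause of the changes was not tested. With the background from detection p-values, 101 genes were higher and 133 lower, UNC13A, GPAM, OCLN, CXCL8, LEF1 and SYNDIG1 passed 2-fold, and drug and bile metabolism had a median of 0.20. LEF1 also passed it with no background, offset 16, median scaling and the authors' values. Median scaling gave mitosis -0.10 and ribosomal proteins 0.14, and the authors' values gave -0.10 and 0.14. Cyclic loess gave NRF2 targets 0.11 and mitosis -0.10. With detection on both arrays, mitosis was at -0.11 and the correlation of probes 0.27. With a detection p-value below 0.01, mitosis was at -0.098. Without a filter, 138 genes were lower, heat shock was at -0.12, mitosis at -0.096, plasma proteins at 0.16 and drug and bile metabolism at 0.080, and 59.2% of genes had probes on the same side, with a correlation of 0.13. The mean over probes gave heat shock -0.17, mitosis -0.098 and plasma proteins 0.10, and took 5 named genes below 2-fold. Both median scaling and the authors' values took ACTR3C below it, and the detection p-value below 0.01 took LRRC41. At or above the median signal, 11 genes were higher and 13 lower, mitosis was at -0.11, adhesion at -0.14 and the correlation of probes 0.28; fewer genes enter there. At 1.5-fold, 376 genes were higher and 281 lower, which turns the imbalance, and at 3-fold 4 and 8. Leaving out technical arrays was not run, since 1 value per probe was given. No paired analysis was possible because each dose has 1 sample. Signal over background limits the dim genes, which have bounds or no fold.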

Other observations

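The split of the stress list was chosen only after its result was seen; the tests of the 2 separate lists were written before their values.

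Several genes outside the rule for named genes, chosen after their values were seen, describe the cells of both samples. S100A4 read 420546 in raw intensity at 0 µg/ml and 409325 at 16 µg/ml, and the imprinted RNA H19 read 374463 and 363098. GSTP1 read 335235 and 337844, the keratin KRT18 158886 and 138321, and CAV1, a caveolar coat protein, 44729 and 38385. The neural cadherin CDH2 was detected in both samples (15098 and 12160), whereas CDH1, which the rule names, and EPCAM and KRT19 were detected in neither. GATA1 was detected at 0 µg/ml only (raw 2296 and 52) and was at least 2.44-fold lower at 16 µg/ml. Its detection p-value there was 0.573, and 1 of 288 other probes within 5 units of its raw intensity had one as low, so this spot was unusual and its bound is uncertain.

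Within the unfolded protein and integrated stress response list, the 9 measured targets of the transcription factor ATF4 were all above 0, with a median of 0.50. The genes named from here on were chosen after their values were seen. TRIB3 was at 0.57, ASNS, which makes asparagine, at 0.50 and PHGDH, which starts serine synthesis, at 0.50. The other 11 members but ATF4 had a median of 0.0095, at percentile 54.6 of their random lists. The hypothesis that ATF4 targets were higher as a group was then tested on 27 measured targets in none of the lists above. Their median was 0.11, with 17 above 0 and 10 below, at percentile 99.15, and the percentile ran from 98.2 to 99.98 over the alternatives. The highest were NUPR1 at 0.87, SLC1A5, an amino acid transporter, at 0.47 and PYCR1 at 0.36. The lowest detected on both arrays were LARS1 at -0.22, ALDH18A1 at -0.21 and EPRS1 at -0.19. A separate list of 18 endoplasmic reticulum chaperone and folding genes had a median of -0.066 at percentile 11.34, which argues against their induction as a group. As a hypothesis for these 2 samples, ATF4 targets may have been induced without the chaperones. ATF4 mRNA itself was at -0.055 by its brighter probe and 0.36 by the other.

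At 2-fold more genes were lower than higher, 68.9% over all genes and 54.17% among the 24 at or above the median signal (exact 95% interval 32.8 to 74.4). At 1.5-fold the direction turned, with 376 genes higher and 281 lower. Whether the dimmer 16 µg/ml array accounts for the excess at 2-fold stays open.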
